A study of Mus musculus with 2 samples.

How the data were processed

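Messenger RNA of splenic marginal zone B cells from male C57BL/6 mice was sequenced in 2 libraries, 1 of CD80high cells and 1 of CD80low cells. CD80 is a costimulatory surface protein and was the marker used to divide the cells. Per the labels' protocols, the mice were wild type and untreated, RNA was isolated with a Maxwell (Promega) method, and directional libraries were made with a kit from MGI. The number of animals behind each library and the other surface markers of the sort are not given in the sources used here.

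Per the submitters' processing notes, the genome build was mm10 and the tools included FastQC 0.11.5, STAR 2.6, Cuffnorm, Cuffdiff and Cufflinks 2.2.1. The expression values deposited by the authors are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), per the file headers. The p-value and q-value of each gene are also the authors', per the file headers, and were made from 1 library per group. The authors' deposited log2 ratio equals log2(CD80high FPKM / CD80low FPKM) to within 4.83e-13 over genes above 0 in both libraries. Whether counting used the strand is not given in the sources used here. FPKM assigns fragments to transcripts by a model, so a gene's value can move with how fragments are shared among its transcripts, and a few abundant genes can shift the values of all others.

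The table held 21853 rows with 21829 gene symbols, and every row was annotated as protein coding. Immunoglobulin, T cell receptor and mitochondrial genes had no rows and were not analysed here, so the list of immunoglobulin constant region genes has no result. The 24 symbols on more than 1 row were summed. The second sheet gave the same values except for 5 genes, and the values of the comparison sheet were used.

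From the deposited FPKM values, a ratio was computed for each gene as log2((CD80high FPKM + 1)/(CD80low FPKM + 1)), which understates the change of low genes. A gene was counted when its mean FPKM was at least 1 and its ratio was at least 2-fold in size. With 1 library per group, no test, p-value or spread between replicates was computed. Folds given in the text are ratios of the FPKM values themselves. For 25 B cell gene lists and 8 lists of markers of other cell types, the median ratio of the measured members (mean FPKM at least 1) was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test of the populations. The ratio, the size rule, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes Cd80; the 12 genes with the largest ratio in each direction among genes with mean FPKM of at least 5, leaving out predicted genes; list members at or above 2-fold, up to 4 in each direction, or where there were none the 2 of highest mean FPKM; and for other cell types the 2 markers of highest mean FPKM.

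The files hold no counts. Low FPKM values fell on steps: of 1191 low genes with a value in both libraries, 62.9% had a ratio within 0.03 (log2) of a ratio of whole numbers up to 6, where evenly spread values would give 25.8%. The steps put 1 fragment in CD80high at 0.04 (log2) above 1 fragment in CD80low, so the libraries had nearly equal depth. The ratios use no transcript length, but the low genes were chosen by FPKM times length (under 0.3 FPKM kb in both libraries). The 62.9% was counted after centring on that 0.04, which came from the same ratios. From single-transcript genes longer than 2000 nucleotides, the totals came to roughly 23600000 fragments for CD80high and 24200000 fragments for CD80low. Fragment numbers per gene were approximated from these steps and the median length of the gene's protein-coding transcripts, and approximate 95% intervals of a fold are exact conditional (Clopper-Pearson) intervals on those numbers. They cover counting error only, and leave out the assignment to transcripts, the library preparation and the variation between animals. This way of estimating depth was chosen after the values were seen. A first version without the length limit, which was dropped, gave steps that differed by -0.15 (log2, CD80high over CD80low), against 0.04 with the limit. The first version was taken to be off because short transcripts have an effective length under the annotated one, which was not tested separately.

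Gene positions and transcript lengths came from GENCODE release M21 (GRCm38, the assembly of mm10), matched by Ensembl identifier. Alternatives were another pseudocount (0.1 or 5), centring, rescaling both libraries to a larger common total, another filter or threshold, another treatment of repeated symbols and unmatched random lists; those added after seeing the data were rescaling to the mean of both totals, an adjustment for transcript length, a condition on the authors' p-value and leaving out markers of other cell types. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data for this comparison with 9955 genes: 4% of 200 unchanged lists and 100% of 200 lists of 15 genes moved by 0.5 (log2) lay outside the central 95% of random lists, the size rule counted 99% of 100 genes changed 3-fold and 100% of 100 genes changed 4-fold, and the intervals held the true ratio in 96.25% of 4000 draws. Simulated counts were drawn independently for each gene, with no trend by transcript length. The 4% thus does not give the share to expect of real lists whose genes vary together. In the data, 17 of 31 lists with a measured member lay outside, where 1.55 were expected by chance. The simulated genes were raised from a mean of at least 1 FPKM. The shares counted thus do not cover genes listed under 1 FPKM in 1 library. Sspn, for example, had 1.80 FPKM in CD80high and 0.405 FPKM in CD80low and was not counted.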

Results

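Gene expression was measured in 2 populations of splenic marginal zone B cells, the B cells that lie at the border of the splenic white pulp and respond early to blood-borne antigen. The CD80high and the CD80low population had 1 library each, so no difference given here has a replicate check. A value above 0 was listed for 13720 genes in CD80high and for 13231 genes in CD80low, and 9955 genes had a mean of at least 1 FPKM. The comparison addresses how the transcriptomes of the 2 populations differ.

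Cd80 itself, the gene of the sort marker (ENSMUSG00000075122, chromosome 16, 38455561 to 38496335, mm10, plus strand), was listed at 4.13 FPKM in CD80high and 1.32 FPKM in CD80low. The fold was 3.12, with an approximate 95% counting interval of 2.30 to 4.36. This checks the labels and is no finding of its own.

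The 2 libraries were close to each other for most genes, with 97.6% of the 9955 genes within 1.5-fold. At least 2-fold higher values were found for 35 genes in CD80high and for 10 genes in CD80low. The counts changed with the weight given to low genes: they were 8 and 0 with a pseudocount of 5, 69 and 25 with a pseudocount of 0.1, and 13 and 2 with only genes of at least 5 FPKM. Rescaling both libraries to the mean of their totals moves every ratio up by 0.16 (log2) before the pseudocount, and the counts were then 51 and 7. Rescaling them to a larger common total also multiplies the FPKM values by 1.81 and 1.63, which weakens the pseudocount and the filter, and gave 91 and 10. Of the 35 genes, 5 are markers of other cell types on the lists fixed beforehand. Those lists are short, so the count can miss genes of such cells. Xcl1 (2.05 against 0 FPKM), Cd7 (2.17 against 0.334 FPKM), Il2rb (2.90 against 0.734 FPKM) and Fcer1g (3.10 against 0.738 FPKM) are among the 35 and on none of them. Tmsb15b2 (5.54 against 2.09 FPKM) is among the 35 and Tmsb15l (1.03 against 3.76 FPKM) among the 10. They overlap on the same strand of chromosome X. Exosc6 (1.86e-05 against 2.61 FPKM) and Gm21992 (0.0297 against 3.18 FPKM), also among the 10, were near 0 in CD80high. Whether the sharing of fragments among transcripts made these differences was not tested.

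**Figure D1:**
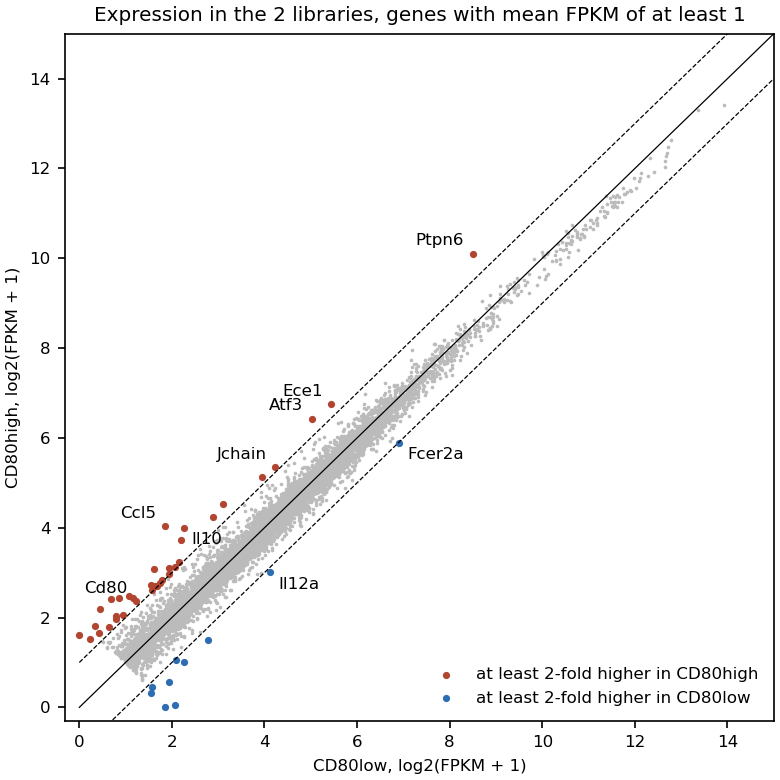
FPKM of each gene in the CD80low library (horizontal axis) and the CD80high library (vertical axis), both as log2(FPKM + 1), for the 9955 genes with a mean of at least 1 FPKM. The solid line marks equal values and the dashed lines a 2-fold difference; 35 genes lie at or above the upper line and 10 at or below the lower.

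Among genes with a mean of at least 5 FPKM, the largest ratio belonged to Ccl5, a chemokine gene used by natural killer and T cells (chromosome 11, 83525778 to 83530518, minus strand). It was listed at 15.4 FPKM in CD80high and 2.601 FPKM in CD80low, a 5.92-fold difference with an approximate 95% counting interval of 4.14 to 8.99. Ccl5 is also on the list of natural killer cell markers, which were higher in CD80high as a group. Il10, the gene of an anti-inflammatory cytokine made by regulatory B cells (chromosome 1, 131019845 to 131024974, plus strand), stood at 12.2 FPKM against 3.55 FPKM, 3.43-fold higher in CD80high (2.77 to 4.26). The transcription factor genes Atf3 (85.3 against 31.4 FPKM), Zbtb20 (22.1 against 7.65 FPKM) and Bhlhe41 (17.8 against 6.45 FPKM) were each more than 2-fold higher in CD80high. So were Tent5c, which encodes a poly(A) polymerase (34.2 against 14.4 FPKM), Jchain, the joining chain of polymeric immunoglobulin (39.9 against 17.8 FPKM), Gpr55, a lipid receptor gene (7.79 against 3.17 FPKM), Cln8 (7.65 against 2.84 FPKM) and Ccnb1ip1 (8.44 against 3.47 FPKM). Ptpn6, which encodes a phosphatase that restrains B cell receptor signalling, was listed at 1101 FPKM in CD80high and 360 FPKM in CD80low, and Ece1 at 107 and 42.3 FPKM. The p-value in the authors' deposited table was 0.246 for Ptpn6, 0.612 for Ece1 and 0.0921 for Ccnb1ip1.

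In the other direction, Il12a, which encodes a subunit shared by interleukins of the IL-12 family (chromosome 3, 68690644 to 68698547, plus strand), had 7.05 FPKM in CD80high and 16.4 FPKM in CD80low, 2.32-fold higher in CD80low (1.98 to 2.74). Fcer2a, the gene of the low-affinity IgE receptor CD23 that is abundant on follicular B cells (chromosome 8, 3681737 to 3694175, minus strand), had 58.6 and 118.5 FPKM, 2.02-fold higher in CD80low (1.89 to 2.16). The ratios of Il12a and Fcer2a, -1.11 and -1.004, lay close to the 2-fold limit. Rescaling to the mean total moves every ratio up by 0.16 (log2) before the pseudocount. The next genes by size stayed under 2-fold on the scale used. They were Mtg1 (6.91 against 14.2 FPKM), Mettl5 (6.88 against 13.4 FPKM), Vpreb3 (28.6 against 52.8 FPKM), Pxdc1 (32.4 against 58.5 FPKM), Col11a2 (3.72 against 7.28 FPKM), Capn5 (3.51 against 6.78 FPKM), Cops9 (59.7 against 103.7 FPKM), Blvrb (15.4 against 26.8 FPKM), Uqcrb (63.4 against 106.7 FPKM) and Mrps14 (18.8 against 32.0 FPKM). Mettl5 overlaps Ssb on the opposite strand (101.5 against 118.4 FPKM), so its values are less certain. In the authors' deposited table the p-value was 0.433 for Mettl5, 0.145 for Uqcrb, 0.129 for Capn5 and 0.0933 for Mtg1.

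Genes of marginal zone B cells were higher in CD80high and genes of follicular B cells lower. Of 14 measured marginal zone genes, 12 were higher in CD80high, with a median ratio of 0.28 (percentile 100 of random lists), and none reached 2-fold; after rescaling to the mean total 0 of the 14 were lower and the median was 0.43. The pair with the highest expression, Cr2 (807 against 837 FPKM) and Mzb1 (396 against 366 FPKM), differed little. Of 11 follicular genes, 9 were lower in CD80high, with a median of -0.23 (percentile 1.96), and Fcer2a alone reached 2-fold, by a small margin (ratio -1.004). With that rescaling, 7 of the 11 were lower and the median was -0.075 (percentile 1.72).

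The list of B-1 cell genes, named for a separate innate-like B cell lineage, had the highest median among the B cell lists, 0.74 (percentile 100). All 15 measured members were higher in CD80high, and 3 reached 2-fold: Ctla4, an inhibitory receptor gene (4.61 against 1.11 FPKM), Bhlhe41, and Ahnak (5.86 against 2.36 FPKM). With a pseudocount of 5 the median was 0.36. At a filter of 5 FPKM it was 0.378 (8 genes), just under the age-associated median of 0.380 (3 genes). Cells of other types, whose markers also rose, cannot be told apart from a difference in the B cells as the source of this rise. The 9 measured age-associated B cell genes had a median of 0.40 (percentile 99.97), and Nkg7 was above 2-fold (3.18 against 0.923 FPKM). Markers of other cell types moved the same way, and 3 of these 9 genes are on their lists; without them the median was 0.35. Memory B cell genes had a median of 0.15 (percentile 99.4, 7 of 12 higher), led by Zbtb32 (4.35 against 0.605 FPKM) and Zbtb20, and the median was 0.30 after rescaling to the mean total. With only genes of at least 5 FPKM it was 0.06, inside the central 95% of random lists (percentile 91.7). Plasma cell genes had a median of 0.11 (percentile 98.8, 9 of 13 higher), and Jchain was their member above 2-fold; rescaled to the mean total the median was 0.27.

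Immediate early and activation genes had a median of 0.12 (percentile 100; 0.27 after rescaling to the mean total), with 20 of 26 members higher in CD80high. Atf3 and Fosl2 (6.78 against 2.85 FPKM) were above 2-fold. Heat shock and dissociation stress genes, which cell handling can induce, were also higher, with a median of 0.10 (percentile 99.5, 10 of 13 higher), while the most abundant, Hsp90ab1 (1128 against 1118 FPKM) and Hspa8 (1112 against 1095 FPKM), were nearly equal. The median of this list was 0.26 after rescaling to the mean total, and against unmatched random lists it lay inside the central 95% (percentile 96.6). Notch target genes (0.15, percentile 98.3, 4 of 5 higher), migration and adhesion genes (0.06, percentile 98.3, 13 of 20 higher) and B cell receptor signalling genes (0.01, percentile 97.8, 12 of 20 higher) lay just outside the central 95% of random lists. Under several alternatives these 3 lists lay inside it, and rescaled to the mean total their medians were 0.28, 0.22 and 0.17. Among them Myc had 323 against 281 FPKM, Dtx1 258 against 252 FPKM, Cxcr4 300.2 against 305 FPKM, and S1pr1 277 against 250.1 FPKM.

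The oxidative phosphorylation list was lower in CD80high. All 26 measured members were lower (24 after rescaling to the mean total), with a median of -0.38 (percentile 0; -0.23 with that rescaling), and none reached 2-fold. Its most abundant members were Cox8a (412 against 488 FPKM) and Cox4i1 (416 against 469 FPKM). Ratios followed transcript length across genes: among 6536 genes with a mean of at least 10 FPKM, the median ratio went from -0.13 to 0.09 between the shortest and the longest of 5 equal groups by transcript length. Pearson's r was 0.40 and Spearman's rho 0.43, across genes, which are not independent replicates. The median transcript length of the oxidative phosphorylation list was 571.5 nucleotides, and after adjustment for length its median ratio was -0.26.

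**Figure D2:**
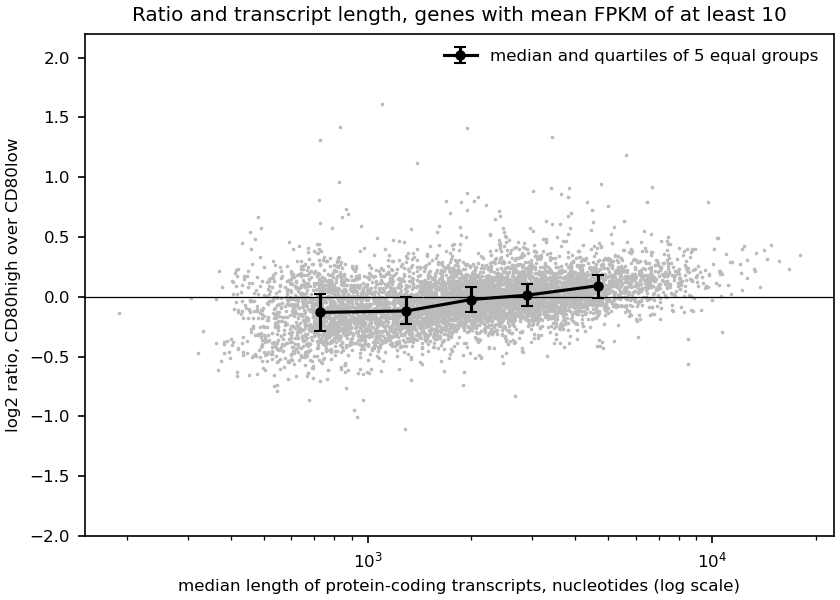
Log2 ratio of CD80high over CD80low (vertical axis) against the median length of a gene's protein-coding transcripts in nucleotides (horizontal axis, log scale), for 6536 genes with a mean of at least 10 FPKM. Black points and bars are the median and quartiles of 5 equal groups of genes by length; the median goes from -0.13 to 0.09.

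The other B cell lists lay within the central 95% of random lists as computed, though 3 of them lay outside it under some alternatives: Toll-like receptor genes in 3 of 10 and against length-matched lists, and germinal centre and antigen presentation genes in 1 of 10 each. Medians were 0.05 for germinal centre genes (percentile 66.5), -0.18 for immature and transitional genes (9.28), -0.06 for endoplasmic reticulum folding and secretion genes (41.4), 0.04 for NF-kappaB targets (91.7), -0.15 for antigen presentation and costimulation genes (15.8), 0.07 for Toll-like receptor genes (97.4) and -0.03 for cytokine and regulatory B cell genes (42.8). They were -0.09 for cell cycle genes (6.24), -0.10 for MYC and ribosome biogenesis genes (9.49), -0.06 for glycolysis genes (43.9), 0.04 for interferon response genes (81.2) and -0.01 for apoptosis and survival genes (70.8). When libraries were rescaled to the mean total, the negative medians in this group turned positive except that of the immature and transitional genes (-0.049), and the positive ones were 0.18 for germinal centre genes, 0.19 for NF-kappaB targets, 0.21 for Toll-like receptor genes and 0.18 for interferon response genes. Il10 and Il12a, the members of the cytokine list at or above 2-fold, went in opposite directions. Abundant members were close in both libraries, such as Cd74 (10068 against 10585 FPKM), B2m (2711 against 3154 FPKM), Hspa5 (485 against 473 FPKM), Spib (328 in both), Cd83 (166 against 161 FPKM), Unc93b1 (537 against 552 FPKM), Gapdh (441 against 475 FPKM) and Mcl1 (254 against 267 FPKM). Odc1, the enzyme that starts polyamine synthesis, was listed at 246 against 144 FPKM, while Npm1 had 524 against 639 FPKM. Bcl6 had 11.98 against 15.5 FPKM and Pcna 107 against 124 FPKM.

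**Figure D3:**
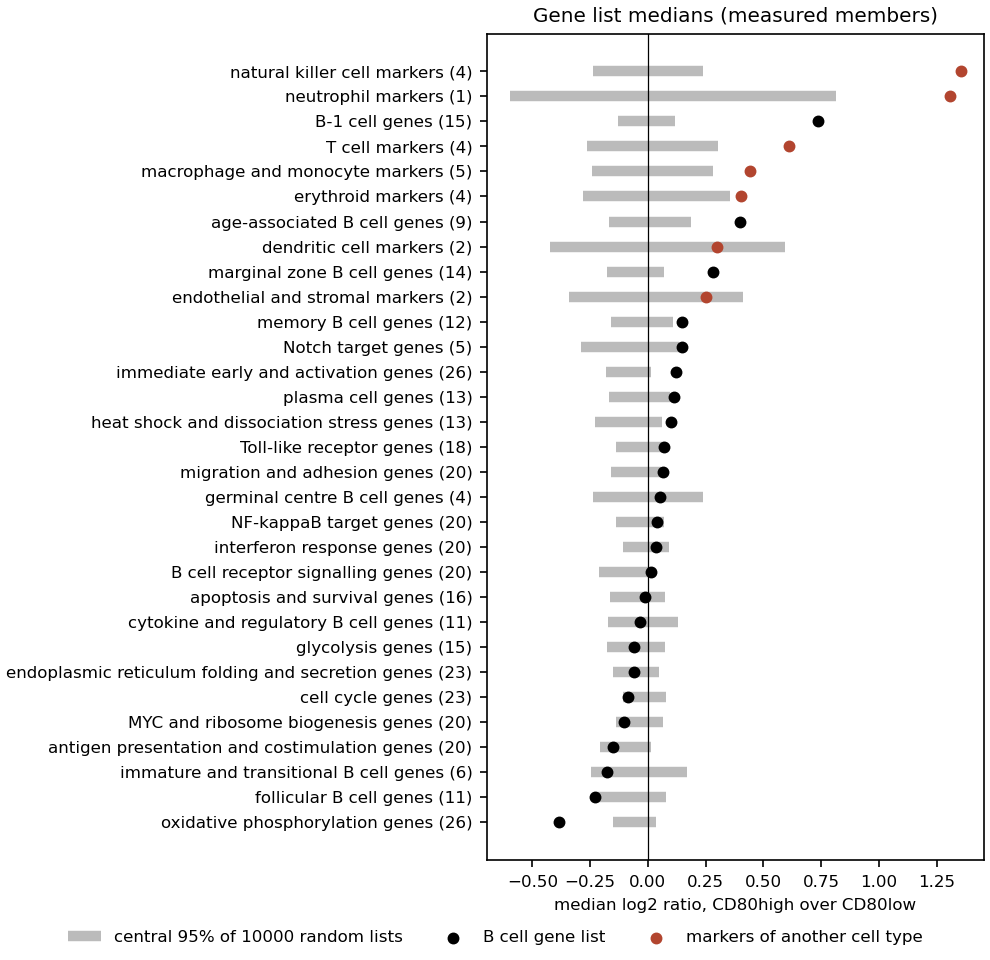
Median log2 ratio of CD80high over CD80low (horizontal axis) for each gene list with a measured member, with the number of measured members in parentheses. Grey bars are the central 95% of 10000 random lists matched on mean expression, black points B cell lists and red points markers of other cell types; the B-1 list lies at 0.74 and the oxidative phosphorylation list at -0.38.

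Markers of other cell types were low in both libraries and mostly higher in CD80high. Of 91 markers with a value above 0, 85 were higher in CD80high (93.4%), where random genes of the same level gave 63.0% on average. All 13 T cell markers and all 18 macrophage and monocyte markers above 0 were higher, as were all 10 neutrophil and all 9 erythroid markers, 9 of 11 natural killer cell markers, 9 of 10 dendritic cell markers, 7 of 8 platelet and megakaryocyte markers and 10 of 12 endothelial and stromal markers. By this share, natural killer (percentile 94.0), dendritic (95.4), platelet (84.6) and endothelial markers (91.6) lay within the central 95% of random lists, and the other 4 lists above it. Among the measured members, the median ratio was 1.36 for natural killer cell markers (4 genes, percentile 100), 1.31 for the neutrophil marker S100a8 (1.89 against 0.166 FPKM, percentile 99.4), 0.61 for T cell markers (4 genes, 99.93), 0.44 for macrophage and monocyte markers (5 genes, 99.5), 0.40 for erythroid markers (4 genes, 98.4), 0.30 for dendritic cell markers (2 genes, 89.0) and 0.25 for endothelial and stromal markers (2 genes, 92.5). The sizes depended on the pseudocount: with 0.1 and 5 they were 2.003 and 0.58 for natural killer cell markers, 2.90 and 0.41 for S100a8, 1.11 and 0.21 for T cell markers, 0.75 and 0.26 for macrophage markers, and 0.64 and 0.15 for erythroid markers. With only genes of at least 5 FPKM, 1 T cell and 1 macrophage marker passed, inside the central 95% (percentiles 55.8 and 95.5), and against length-matched lists the neutrophil (95.2) and erythroid (96.7) medians lay inside it. Abundant markers went both ways: Ccl5 differed 5.92-fold, while Lck had 15.5 against 15.2 FPKM, Prf1 10.01 against 10.6 FPKM and Pecam1 69.6 against 72.3 FPKM. Cd68 had 9.16 against 6.81 FPKM, Hmox1 4.78 against 2.04 FPKM, Cdh5 3.11 against 1.79 FPKM, Hba-a2 2.37 against 1.21 FPKM, Flt3 2.15 against 1.94 FPKM and Itga2b 0.322 against 0.170 FPKM.

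**Figure D4:**
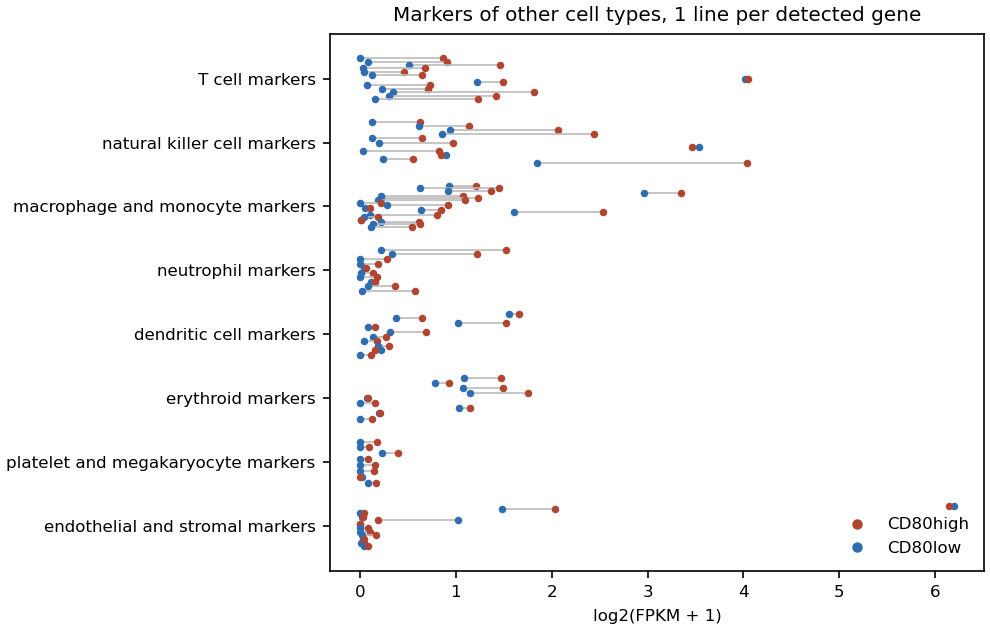
Expression of each marker of another cell type above 0 in either library, as log2(FPKM + 1) on the horizontal axis, grouped by list. Red points are CD80high and blue points CD80low, and a line joins the values of a gene; 85 of 91 markers are higher in CD80high.

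In the authors' deposited table, 10814 rows were tested and 106 were called at 2-fold with a p-value of at most 0.05, 95 of them higher in CD80high and 11 lower. Of these 106 calls in the authors' deposited table, 52 had a mean under 1 FPKM and 15 had a q-value of at most 0.05. The smallest q-value in the authors' deposited table was 0.0360, shared by Atf3, Jchain, Tent5c, Ahnak, Fosl2, Fcer2a, Grip2, Prdm1 and Rap1gap2. Also at that q-value were Cd3e, Clec2g, Hp, Krt5, Krt6b and Krt16, each listed at 0 FPKM in CD80low and under 1 FPKM in CD80high. Of the genes counted by size here, 26 of the 35 higher and 4 of the 10 lower had a p-value of at most 0.05 in the authors' deposited table. Those p-values compare 2 libraries and not the populations.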

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

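Alternatives added after the data were seen are rescaling to the mean total, the length adjustment, the condition on the authors' p-value and the exclusion of markers of other cell types. The raw counts alternative was not run because the files hold no counts. No paired analysis was possible because each group has 1 library. Of the single-gene values, 310 moved by less than the approximate counting interval and 70 moved by more; of the list medians, 221 moved by less than 1 SD of random-list medians and 86 by more. No list that lay outside the central 95% of random lists as computed changed the sign of its median. Medians of lists inside it did, such as germinal centre genes (0.05, and -0.11 with a filter of 5 FPKM). Cell cycle genes did as well (-0.09, and 0.062 rescaled to the mean total). Some alternatives could not move these values. Centring shifts a list and its random lists alike, so it could not change a percentile. Unmatched random lists leave the medians as they were, and taking the highest row of a repeated symbol changed no list median. Both are among the medians counted as moving by less. The lists of marginal zone, follicular, B-1, age-associated, plasma cell, immediate early and oxidative phosphorylation genes lay outside the central 95% of random lists in all 10 alternatives. With a filter of 5 FPKM the memory (percentile 91.7), T cell (55.8, 1 gene) and macrophage lists (95.5, 1 gene) lay inside it, with unmatched lists the heat shock list (96.6), and against length-matched lists the neutrophil (95.2) and erythroid lists (96.7). The Notch target list did so in 7 of 10, the B cell receptor signalling list in 6 of 10 and the migration list in 3 of 10. Against length-matched lists, which are not among the 10, these 3 lists also lay inside it (percentiles 96.8, 86.8 and 91.2). In the other direction, the Toll-like receptor list lay outside with a pseudocount of 0.1 (percentile 97.54), a filter of 5 FPKM (97.77) and no filter (97.93), and against length-matched lists (99.04); the germinal centre list did so at the larger common total (98.5) and the antigen presentation list with unmatched lists (0.67). The cause was not tested, except where the setting itself changes the number of genes or shifts all ratios.

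The count higher in CD80high (35) was 69 with a pseudocount of 0.1, 8 with a pseudocount of 5, 91 at the larger common total, 13 with a filter of 5 FPKM, 150 at 1.5-fold and 7 at 3-fold. The count higher in CD80low (10) was 25, 0, 10, 2, 89 and 2 in the same order, and 4 with an authors' p-value of at most 0.05. Centring gave 37 and 9, and rescaling to the mean total 51 and 7. The Cd80 ratio of 1.14 was 0.53 with a pseudocount of 5.

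Rescaling to a larger common total and, scaling alone, to the mean total gave, in this order, medians of 0.44 and 0.43 (marginal zone), -0.076 and -0.075 (follicular), 0.33 and 0.30 (memory), 0.91 and 0.88 (B-1), 0.56 and 0.54 (age-associated), 0.42 and 0.18 (germinal centre), 0.090 and -0.049 (immature), 0.28 and 0.27 (plasma cell), 0.092 and 0.091 (endoplasmic reticulum), 0.17 and 0.17 (B cell receptor signalling), 0.28 and 0.27 (immediate early), 0.19 and 0.19 (NF-kappaB), 0.0036 and 0.0036 (antigen presentation), 0.22 and 0.21 (Toll-like receptor), 0.22 and 0.22 (migration), 0.075 and 0.12 (cytokine), 0.063 and 0.062 (cell cycle), 0.049 and 0.048 (MYC), 0.094 and 0.094 (glycolysis), -0.23 and -0.23 (oxidative phosphorylation), 0.18 and 0.18 (interferon), 0.15 and 0.14 (apoptosis) and 0.26 and 0.26 (heat shock), and 0.28 for Notch targets at the mean total. The first also weakens the pseudocount and lets more members of 7 B cell lists pass the filter, among them 6 and not 4 for germinal centre, 7 and not 6 for immature and 14 and not 12 for memory genes.

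Rescaled to the larger common total, medians of markers of other cell types were 1.41 (T cell), 1.10 (natural killer), 1.13 (macrophage) and 0.58 (erythroid), with 6, 6, 9 and 5 members where 4, 4, 5 and 4 were measured. With pseudocounts of 0.1 and 5 they were 1.11 and 0.21 (T cell), 2.003 and 0.58 (natural killer), 0.75 and 0.26 (macrophage), 2.90 and 0.41 (neutrophil) and 0.64 and 0.15 (erythroid). With no filter they were 0.52 (natural killer), 0.23 (neutrophil), 0.15 (erythroid) and 0.036 (endothelial), and with a filter of 5 FPKM 0.032 (T cell), 1.06 (natural killer) and -0.054 (endothelial).

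For the B cell lists, with a filter of 5 FPKM, medians were 0.059 (memory), 0.38 (B-1), -0.11 (germinal centre), -0.032 (immature) and -0.12 (cytokine). With no filter they were 0.65 (B-1), 0.00061 (immature) and 0.063 (cytokine). The B-1 median was 0.83 with a pseudocount of 0.1 and 0.36 with 5, and the age-associated median 0.29 with 5. After the length adjustment, medians were 0.49 (age-associated), 0.23 (plasma cell), 0.016 (endoplasmic reticulum), 0.21 (immediate early), -0.067 (antigen presentation), -0.26 (oxidative phosphorylation) and 0.090 (apoptosis). Depth limits the genes near 1 FPKM most.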

Other observations

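The tests on depth, on cells of other types, on the share of B cells and on ribosomal proteins were chosen after the related result was seen; the length tests and the keratinocyte test were chosen before their values were seen. The comparison of the marker lists and keratinocyte genes with expression-matched draws, the dealing of markers to lists, and the use of the rescaled ribosomal median were added after their values were seen, and made those readings stricter than first set. For the receptor list the measure of spread was changed more than once after its values were seen. With a bound of 0.1 alone a lower share of B cells was argued against, and with the SD of all members it was open. The measures given below leave it open. The genes in the next paragraph were chosen after their values were seen.

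Outside the genes named by rule, 69 genes had a mean of at least 5 FPKM, a ratio of at least 1.5-fold and a p-value of at most 0.05 in the authors' deposited table, 49 higher in CD80high and 20 lower. The higher ones include Serpine2 (14.4 against 6.93 FPKM), Dnase1l3 (21.7 against 10.8 FPKM), Nid1 (10.6 against 5.09 FPKM), Sirpa (15.2 against 7.90 FPKM), Plxnd1 (59.5 against 32.9 FPKM), Csf2rb (37.6 against 20.7 FPKM), Tnfaip3, a brake on NF-kappaB signalling (81.2 against 49.0 FPKM), Ahr, a ligand-activated transcription factor (27.7 against 17.5 FPKM), and Cd274, which encodes PD-L1 (106.8 against 69.6 FPKM). The lower ones include Slamf1 (5.10 against 8.76 FPKM), Hvcn1, a proton channel gene (88.5 against 138.3 FPKM), Neurl3 (36.5 against 56.98 FPKM) and the ribosomal protein gene Rpl38 (4216 against 6457 FPKM). The p-values used in this choice are not corrected for the number of rows tested and come from 1 library per group. They do not show that these genes differ between the populations. Prdm1, which drives plasma cell differentiation, had 5.83 against 2.42 FPKM and lay just under 2-fold on the scale used (ratio 0.996).

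Markers of unrelated cell types were higher together in CD80high. A difference in depth is argued against, since the share of markers higher lay at percentile 100 of expression-matched draws. Cells of other types in the CD80high sample cannot be told apart from a difference in the B cells: 8 of 8 lists had 70% or more of their members higher, but with 85 of 91 markers higher, dealing the markers to the lists at random gave at least 7 such lists each time. The labels name B cells and give no gate that would remove such cells, and the levels were low, with the T cell gene Cd3g at 1.75 against 0.431 FPKM and the macrophage gene C1qb at 1.35 against 0.169 FPKM. Of 15 detected keratinocyte genes not looked at before, 11 (73.3%) were higher in CD80high, which meets the bound of 70% set beforehand. Expression-matched draws reached that share often (mean 61.0%, percentile 82.9). The share counts direction and not size. Among those lower, Ly6d (1525 against 1723 FPKM) and Sfn (17.7 against 19.3 FPKM) were well above 0 in both libraries. Those higher included Krt14 (1.26 against 0.0248 FPKM) and Lgals7 (1.25 against 0.0694 FPKM), examples chosen after their values were seen. Of all 22 detected, some seen before the test, 12 were listed at 0 in CD80low and none in CD80high. Skin cells or their RNA thus stay open as the source of Krt5 and Krt16, both listed at 0 in CD80low and at 0.580 and 0.460 FPKM in CD80high.

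Lists of B cell subsets moved apart, with marginal zone and B-1 genes higher and follicular genes lower in CD80high. A lower share of B cells stays open as a cause for the follicular genes. The B cell receptor signalling list had a median of 0.011 where the follicular list had -0.23, a gap of 0.24. That gap exceeds the bound of 0.1 set for it and the members' scaled median absolute deviation of 0.19. Its 95% bootstrap interval over genes (0.046 to 0.46) reaches below the bound, though, and genes of 1 pair of libraries are not independent replicates. At or below the follicular median lay 3 of 20 members (Cd79a -0.29, Cd79b -0.26 and Cd72 -0.30, named after their values were seen). The SD of the members, 0.39, exceeds the gap, but it was 0.15 without Ptpn6, which was higher in CD80high. Transcript length is argued against as the whole cause, since the difference between the marginal zone and follicular medians and the B-1 median both lay at percentile 100 of length-matched random lists. For the B-1 list, 1 of 15 members gained more FPKM than the marker that gained most (Ccl5, 12.8 FPKM). Members at a few FPKM, such as Ctla4 (4.61 FPKM in CD80high) and Ahnak (5.86 FPKM), could not gain that much from any source. This comparison thus decides nothing, and cells of other types cannot be told apart from a difference in the B cells. A different share of follicular or B-1 cells within the 2 sorts was not tested and stays open beside a difference between the populations.

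Oxidative phosphorylation genes were lower in CD80high. Transcript length is argued against as the whole cause, since the median lay at percentile 0.28 of length-matched lists, although those lists were themselves mostly negative (central 95% from -0.34 to -0.09). The lower values were not particular to this list as deposited: all 80 measured ribosomal protein genes were lower in CD80high with a median of -0.32 (73 lower and a median of -0.17 after rescaling to the mean total), and they made up 30.8% of the FPKM sum in CD80high and 35.1% in CD80low. A wider shift of short, abundant transcripts cannot be told apart from a change in this list. The ribosomal median as deposited met the bound of -0.2 set for it, and the rescaled one missed it. The same rescaling took the oxidative phosphorylation median from -0.38 to -0.23. Under either scaling both sets had a negative median, which either reading allows. No biological explanation was tested.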
